A study of Rattus norvegicus with 24 samples.

How the data were processed

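Total RNA from a piece of the middle of the soleus of 24 female rats, about 14 weeks old, was labelled with Cy3 and hybridised to 1 Agilent one-colour array per rat, per the labels. The scanner files hold spot intensity values from Agilent Feature Extraction, which subtracted background and corrected spatial trends within each array but not between arrays, per the file headers. The submitters' processing notes name version 11.5.11.1 and the file headers version 11.5.1.1. The authors also deposited a table of log2 values for the same arrays. Its 24 columns share 1 distribution to within 0.0031 and a median of 6.26, and each ranks the probes as the processed signal of its array does (Spearman correlation 1), so it was read as quantile normalized log2 signal; the tool that made it is not given in the sources used here. No column of that table went unmatched to a sample. Group names and replicate numbers came from the sample titles, and the design text gives 8 rats per group. p-values of single genes therefore measure the spread between rats, and the number of arrays limits the precision. p-values of the gene list test at a preset correlation rest on the spread between genes instead.

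Each array has 62976 spots, of which 4259 control spots were left out. The processed signal was put on a log2 scale and each array's 75th percentile over the other spots was subtracted. Spots marked as outliers by Feature Extraction were left out and the spots of 1 probe averaged, giving 30367 probes; no spot was saturated. Probes were named through the RefSeq gene table of assembly GRCr8 by accession (18634 probes) or kept the name in the files (5638), and 6095 had no name; its coordinates were not used, since the array was designed on an older build. A gene was represented by its probe with the highest mean over all arrays. Features had to be well above background on at least 8 of 24 arrays, which left 20350, of which 15861 had a gene name. Of 2768 genes with several probes in the filter, 1192, 1225 and 1235 had probes that differed in sign in the 3 comparisons (detrained minus sedentary, trained minus sedentary, trained minus detrained). No pair of arrays was identical, and the highest correlation between arrays was 0.995.

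All 24 arrays were fitted together in limma 3.58.1 (R 4.3.3) with group and slide as terms, where slide was read from the array identifiers. The moderated test had 19 residual and 2.87 prior degrees of freedom, and p was adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. 30 gene lists (20 gene groups and 10 cell types, with 779 members, 56 of which had no feature) were tested with camera at a preset correlation of 0.01 and adjusted over the lists. The SE of a list's mean is that of the mean value per array in the same model. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison, the 10 largest rises and falls past the threshold, up to 4 members of each list past it, the 5 named genes with the smallest p where none passed, the 3 members with the smallest p in the direction of each called list, and a fixed set of metabolic, contractile and stress genes in the comparisons against sedentary muscle. Of that set, Hspa1a had no probe, and Pax7 and Mstn were well above background on 3 and 6 arrays, under the limit of 8. Other genes are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

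The alternatives fixed in advance were quantile normalization, normexp background correction (offset 50), the authors' normalized table, no filter or a filter on all 24 arrays, no slide term, slide as a random block, slide with array row, single slides, the replicate number as a block, only the groups compared, array weights, a trended robust prior, all probes, other thresholds, each array left out, and an estimated correlation in camera. The normexp correction had been planned on mean spot signals; the files used hold median spot signals, and those were used. Fits without slide 3 and without the 4 noisiest trained arrays, array weights in camera, and exact permutations of the lists' means within slides were added after the data were seen. An exact permutation took every assignment of the arrays of 1 slide to the groups present there, two-sided, on the list's mean per array. Splits of the arrays into groups of the same sizes, with and without each slide's group sizes kept, were also added then; 100 were drawn, or all 15 where no more exist.

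The fit was tested on simulated data with each feature's spread over these arrays and 200 of 20350 features changed. Of 50 features each, 32%, 70%, 90% and 94% were recovered at 1.5, 2, 3 and 4-fold changes in the layout of detrained minus sedentary, with 9 false calls, and 40%, 78%, 98% and 98% in that of trained minus sedentary, with 7 false calls. With no change simulated, 0 features were called in either. In the layout of detrained minus sedentary, a list shifted by 0.3 was called and 0 of the 29 other lists were. The simulated genes varied independently and with the same spread on every array. The simulation therefore cannot show how often correlated genes or noisy arrays give false calls.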

Results

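Gene expression was measured with 24 one-colour Agilent arrays in soleus, a postural hindlimb muscle made mostly of slow fibres, from female rats, with 1 array per rat and 8 rats in each of 3 groups. Sedentary rats (SED) lived in ordinary cages for 8 weeks, trained rats (TR) ran on wheels at will for 8 weeks, and detrained rats (DETR) ran for 4 weeks and then had no wheel for 4 weeks. Every rat then ran for 1 h at 20 m/min and the muscle was taken 24 h later, so the groups were compared after the same bout; resting muscle was not analysed here. The question the design poses is whether earlier running, kept up or stopped, alters the muscle's expression after that bout. Values are log2 signals relative to each array's 75th percentile, and differences are log2 with the standard error (SE) from a model with slide as a term. The arrays lay on 3 slides of 8. Slide 1 held 2 SED and 6 DETR arrays, slide 2 held 4 SED and 4 TR arrays, and slide 3 held 2 SED, 2 DETR and 4 TR arrays. The 75th percentile of signal was 816.7 to 1184 on slide 1, 562.3 to 1493 on slide 2 and 95.5 to 339 on slide 3, which was scanned on another day. The mean share of probes well above background was 72.2% ± 5.4 (SD, n = 8) in SED, 75.5% ± 8.8 in DETR and 64.3% ± 12 in TR. It was 47.9% to 53.6% on TR 5, TR 7 and TR 8. The median coefficient of variation (CV) between spots of one probe was 31.5% on TR 2 and 4.29% to 9.24% on the other TR arrays.

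**Figure D1:**
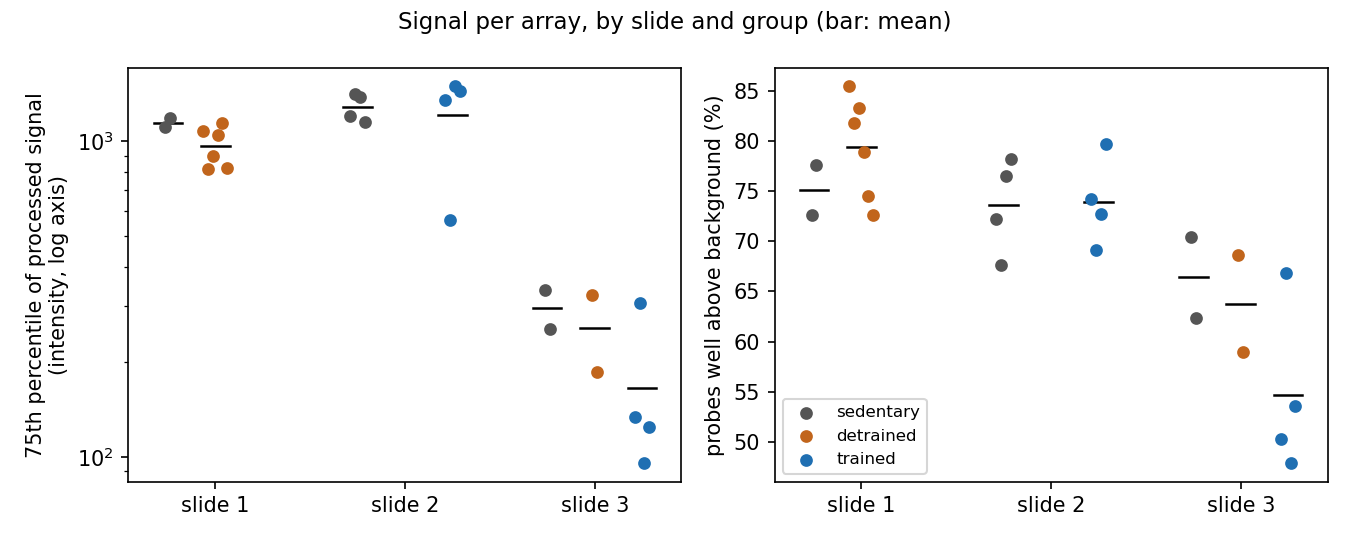
The left panel plots each array's 75th percentile of processed signal (intensity, log axis) and the right panel its share of probes well above background (%), by slide, with points coloured by group and a bar at each mean. Arrays on slide 3 lie between 95.5 and 339 in signal, and those on slides 1 and 2 between 562.3 and 1493.

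Detrained muscle had lower values than sedentary muscle for 30 of the 33 measured genes of fatty acid uptake and oxidation, with a mean log2 difference of -0.34 ± 0.14 (SE over arrays, n = 8 per group). Cpt2, which completes carnitine-dependent entry of fatty acids into mitochondria, differed by -0.42 ± 0.13, and Hadhb and Eci2, which act in beta-oxidation, by -0.40 ± 0.13 and -0.42 ± 0.14. Ucp3, a mitochondrial carrier protein, and Pdk4, which restrains glucose oxidation, differed by -1.19 ± 0.81 and -0.82 ± 0.56. The list passed camera, limma's test of a gene list against all other genes, with adjusted p = 4.57e-15 at a preset correlation between genes, and did not pass with an estimated correlation (adjusted p = 0.104). The shift was -0.32 within slide 1, -0.39 within slide 3 and -0.18 without the slide term. These slides held 2 SED arrays each. The 4 SED arrays of slide 2 shared no slide with a DETR array. With the slide term they entered this difference only through the TR arrays. An exact permutation of group labels within slides, two-sided and added after the data were seen, gave p = 0.0774 for the list's mean, with 168 arrangements and a smallest possible p of 0.00595. No member passed with p adjusted over the list alone (smallest 0.0551).

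**Figure D2:**
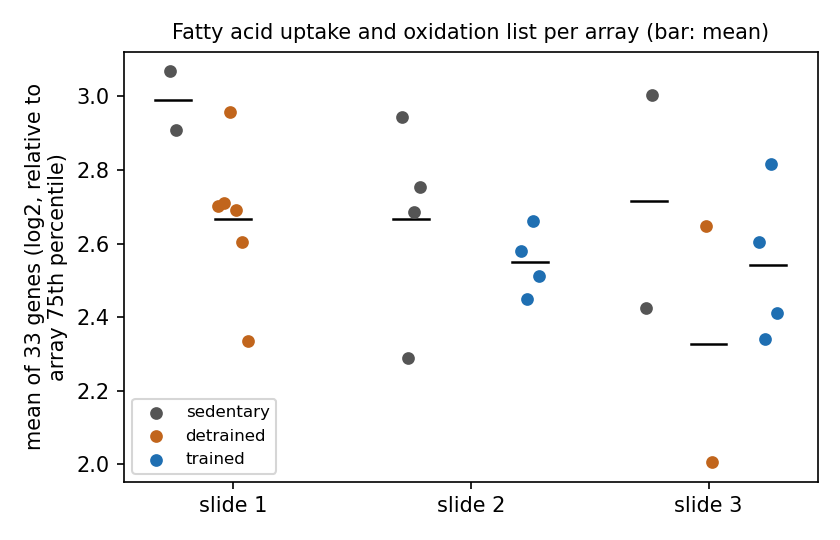
Each point is the mean over the 33 measured genes of fatty acid uptake and oxidation on 1 array (log2, relative to the array's 75th percentile), by slide and group, with a bar at each mean. The detrained bar lies below the sedentary bar on both slides that hold these groups, by 0.32 on slide 1 and 0.39 on slide 3 before any model, and points of the groups overlap on each slide.

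Of the other lists, 5 passed camera between detrained and sedentary muscle, and none of them passed with an estimated correlation. Glycolysis and glycogen genes were lower by a mean of -0.08 ± 0.05 with 15 of 25 members lower, among them Pgm1 (-0.33 ± 0.16), Gpd1 (-0.47 ± 0.24) and Fbp2 (-0.47 ± 0.27). Their mean was 0.01 within slide 1, -0.24 within slide 3 and 0.07 without the slide term. Interferon response genes were higher by 0.23 ± 0.16 with 27 of 29 higher, including the RNA sensor Ifih1 (0.56 ± 0.22), Ifi44 (0.61 ± 0.37) and Mx2 (0.18 ± 0.11). The interferon mean was 0.17 within slide 1 and 0.13 within slide 3. Ribosomal protein genes were higher by 0.10 ± 0.09 with 34 of 42 higher, including Rpl23 (0.21 ± 0.15), Rplp0 (0.17 ± 0.12) and Rplp1 (0.25 ± 0.18). The ribosomal mean was 0.03 within slide 1 and 0.06 within slide 3. Adipocyte markers were lower by -0.21 ± 0.15 with 10 of 14 lower, including the glycerol channel Aqp7 (-0.93 ± 0.30), Pck1 (-0.86 ± 0.58, well above background on 3 SED, 5 DETR and 5 TR arrays) and Cfd (-0.29 ± 0.24). The adipocyte mean was -0.13 within slide 1, -0.29 within slide 3 and 0.01 without the slide term. Tendon markers were lower by -0.52 ± 0.49 with 10 of 13 lower, including Kera (-1.52 ± 1.07), Tnmd (-1.32 ± 0.99) and Comp (-0.84 ± 0.63). The tendon mean was -0.30 within slide 1 and -0.32 within slide 3. The interferon, ribosomal and tendon means from the model were larger in size than those on either slide. The model also compares these groups indirectly, through the trained arrays of slides 2 and 3. Camera was not run on only the detrained and sedentary arrays of all slides. The adjusted p from camera was 0.0447 for glycolysis, 0.00758 for interferon, 0.0472 for ribosomal proteins, 0.0336 for adipocytes and 0.0336 for tendon. With an estimated correlation the adjusted p was 0.719, 0.755, 0.920, 0.719 and 0.755 in that order.

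No single gene passed limma at adjusted p 0.05 between detrained and sedentary muscle (0 of 20350 features), against 800 at an unadjusted p under 0.05 and 15 called when arrays were weighted by their quality. With no change, 1018 features would be expected under 0.05, and 14 of 100 splits of the arrays that kept each slide's group sizes gave at least 800. The smallest p-values belonged to the growth factor gene Fgf2 (0.64 ± 0.13, adjusted p = 1), the kinase gene Dyrk2 (0.78 ± 0.18), Qser1 (0.50 ± 0.12) and the less described LOC685989 (1.90 ± 0.42, well above background on only 2 SED, 4 DETR and 2 TR arrays) and RGD1564676 (0.54 ± 0.13). Fgf2 was higher within slide 1 by 0.67 and within slide 3 by 0.61, and with array weights Fgf2 and Dyrk2 passed, each with adjusted p = 0.0482. Among genes fixed in advance, the inducible chaperone gene Hspa1b differed by 0.64 ± 0.24, the mitochondrial regulator Ppargc1a by 0.13 ± 0.18, and the hexokinase gene Hk2 by 0.15 ± 0.14. The glucose transporter gene Slc2a4 differed by -0.04 ± 0.10. Cs, of the citrate cycle, differed by 0.04 ± 0.13, Vegfa by 0.07 ± 0.16, and Hmox1 by 0.10 ± 0.26. The atrophy genes Fbxo32 and Trim63 differed by 0.12 ± 0.13 and -0.16 ± 0.16, Myog by 0.20 ± 0.16, Myod1 by -0.07 ± 0.34 and Nr4a3 by -0.43 ± 0.68. The myosin genes differed by 0.18 ± 0.13 for slow Myh7, -0.25 ± 1.41 for Myh2, -1.63 ± 1.41 for Myh1 and -0.13 ± 0.84 for Myh4. Myh7 was at -0.11 after quantile normalization and -0.10 in the authors' normalized table.

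Trained muscle had lower values than sedentary muscle for 15 of 17 genes of the fast fibre sarcomere and calcium list, with a mean log2 difference of -0.92 ± 0.51 (SE over arrays, n = 8 per group). Mybpc2, a fast myosin-binding protein, differed by -2.42 ± 0.94, and the fast myosin heavy chains Myh1 and Myh2 by -2.71 ± 1.22 and -2.51 ± 1.22. Tnni2, the fast troponin I, lay at 0.18 to 1.60 on SED 3, TR 1, TR 2, TR 4 and TR 5 and at 5.83 to 8.50 on the other 19 arrays, a gene chosen after its values were seen. Myl1, a fast light chain on the same list, was higher by 0.41 ± 0.08. The list's mean was -0.77 within slide 2 and -1.51 within slide 3, camera gave adjusted p = 0.0423, and an estimated correlation gave adjusted p = 0.744. The exact permutation within slides gave p = 0.133. The list passed camera in 6 of 15 settings and in 12 of the 24 fits that left out 1 array, and lost its call without SED 1, SED 4, SED 5, SED 6, SED 7, DETR 1, TR 1, TR 2, TR 4, TR 5, TR 7 or TR 8. Slow Myh7 differed by -0.09 ± 0.11, and by 0.24 without the slide term.

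**Figure D3:**
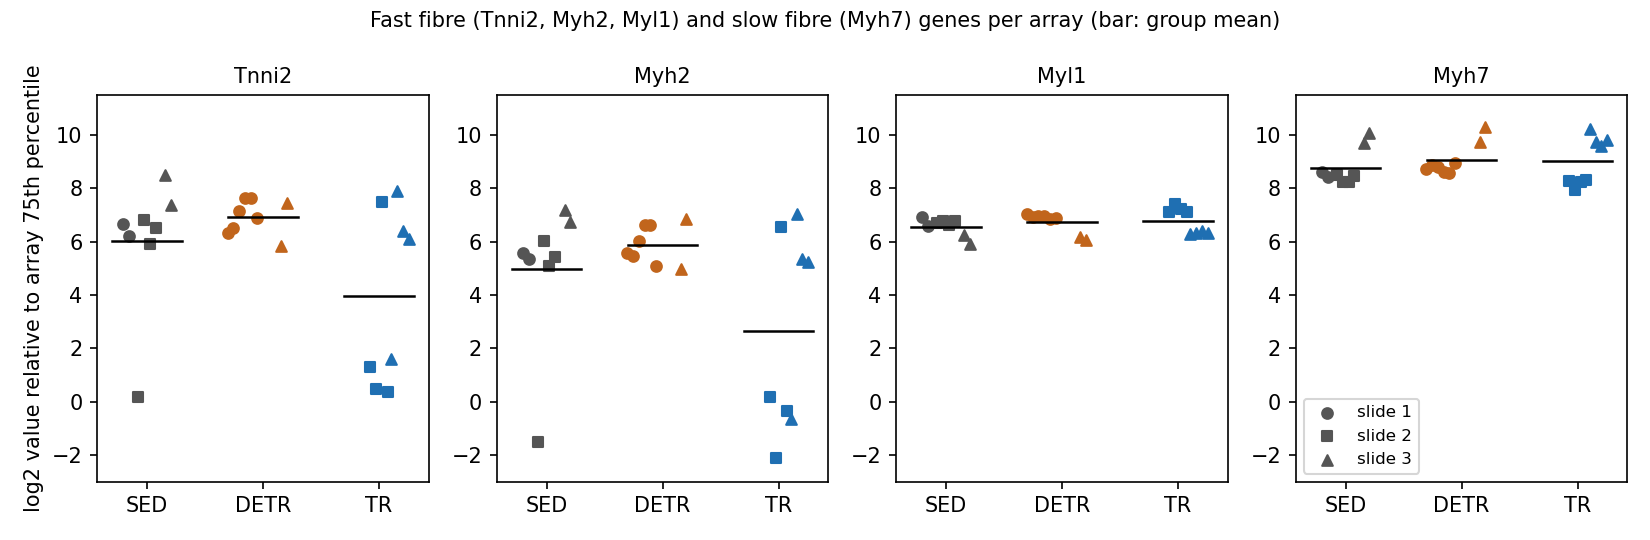
Each point is 1 array's log2 value relative to its 75th percentile for the fast fibre genes Tnni2, Myh2 and Myl1 and the slow fibre gene Myh7, by group, with the marker showing the slide and a bar at the group mean. Tnni2 lies at 0.18 to 1.60 on 1 sedentary and 4 trained arrays and at 5.83 to 8.50 on the rest, and Myh2 is low on the same arrays.

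Macrophage markers were higher in trained than in sedentary muscle by a mean of 0.34 ± 0.14, with 15 of 17 higher and 3 passing when adjusted over the list alone. Mrc1, a mannose receptor of tissue macrophages that was well above background on only 5 SED, 6 DETR and 4 TR arrays, differed by 0.75 ± 0.22, the protease Ctss by 0.55 ± 0.19 and Lyve1 by 0.56 ± 0.19. The macrophage mean was 0.29 within slide 2 and 0.26 within slide 3. Cell cycle genes were lower by -0.17 ± 0.09, with 15 of 25 lower and 4 passing when adjusted over the list alone. With normexp background correction the list did not pass; its mean was 0.10, still below the median of all genes, which had moved to 0.15. Rrm2, which supplies deoxynucleotides for DNA synthesis, differed by -1.18 ± 0.26, the mitotic kinase Aurka by -0.66 ± 0.16 and Cdk1 by -0.73 ± 0.19. The cell cycle mean was -0.22 within slide 2 and -0.17 within slide 3. Ribosomal protein genes were lower by -0.15 ± 0.08 with 38 of 42 lower, including Rpl24 (-0.21 ± 0.10) and Rpl35 (-0.19 ± 0.10). Their mean was -0.01 within slide 2 and -0.30 within the dim slide 3. Tendon markers were lower by -0.68 ± 0.42 with 11 of 13 lower, including Col2a1 (-0.42 ± 0.22), Fmod (-1.40 ± 0.80) and Comp (-0.95 ± 0.55). Their mean was -1.20 within slide 2 and -0.07 within slide 3. Camera gave adjusted p = 4.38e-05 for macrophages, 0.00277 for the cell cycle, 1.6e-05 for ribosomal proteins and 0.00576 for tendon. With an estimated correlation the adjusted p was 0.688, 0.688, 0.727 and 0.688. The exact permutation within slides gave p = 0.103, 0.0286, 0.170 and 0.149 (0.371 for the cell cycle once adjusted over the 30 lists).

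No single gene passed limma at adjusted p 0.05 between trained and sedentary muscle (0 of 20350 features), against 2121 at an unadjusted p under 0.05 and 107 called when arrays were weighted by their quality. With no change, 1018 would be expected under 0.05, and 25 of 100 splits that kept each slide's group sizes gave at least 2121. Of the 107, 52 were higher and 55 lower. Among the smallest p-values were those of Kif22 (-0.91 ± 0.16), the complement gene C6 (1.19 ± 0.23), LOC102549710 (-0.80 ± 0.15) and Myl1, each with adjusted p = 0.136. Leaving out 1 array at a time gave 3 genes without SED 3, 2 without SED 7, 2 without DETR 7, 1 without DETR 8, 2 without TR 2 and 3 without TR 6. Among genes fixed in advance, Myod1, a regulator of muscle cell differentiation, differed by -0.95 ± 0.29 (adjusted p = 0.299), Nr4a3 by -1.14 ± 0.59, Ucp3 by -1.16 ± 0.70, Pdk4 by -0.35 ± 0.48 and Myog by -0.21 ± 0.14. Ppargc1a differed by 0.14 ± 0.16, Hk2 by -0.09 ± 0.12, Slc2a4 by -0.04 ± 0.09, Cs by 0.04 ± 0.11, and Vegfa by 0.15 ± 0.14. Hspa1b differed by 0.12 ± 0.20, Hmox1 by 0.13 ± 0.22, Fbxo32 by 0.06 ± 0.11, Trim63 by 0.19 ± 0.14 and Myh4 by -0.93 ± 0.73.

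Trained muscle had higher values than detrained muscle for 29 of 33 genes of fatty acid uptake and oxidation, with a mean log2 difference of 0.21 ± 0.15 (SE over arrays, n = 8 per group). Both this shift and that between detrained and sedentary muscle use the detrained arrays. Between trained and sedentary muscle the list's mean was -0.13 ± 0.12 and its median 0.005, with 17 genes higher and 16 lower (camera adjusted p = 0.670). The difference between trained and detrained muscle was 0.22 within slide 3 and -0.03 without the slide term. It was 0.06 without DETR 8 and 0.34 without DETR 7, so its size rests on single arrays. Hadhb differed by 0.47 ± 0.14, Eci2 by 0.44 ± 0.15 and the fatty acid binding protein gene Fabp3 by 0.58 ± 0.20. Adipocyte markers were higher by 0.58 ± 0.17 with 12 of 14 higher, including Pck1 (2.23 ± 0.64), the complement factor gene Cfd (0.87 ± 0.27) and Adipoq, which encodes adiponectin (1.21 ± 0.46). Macrophage markers were higher by 0.44 ± 0.17 with 16 of 17 higher, including Lyve1 (0.78 ± 0.25), Ctss (0.67 ± 0.24) and Mrc1 (1.04 ± 0.28), which was at -1.19 in the authors' normalized table. Smooth muscle and pericyte markers were higher by 0.27 ± 0.14 with 12 of 15 higher, including Lmod1 (1.74 ± 0.37, well above background on 4 SED, 6 DETR and 4 TR arrays), Actg2 (0.49 ± 0.28) and Notch3 (0.51 ± 0.30). Atrophy and proteasome genes were higher by 0.12 ± 0.06 with 22 of 30 higher, including Ctsl (0.29 ± 0.12), Eif4ebp1 (0.47 ± 0.21) and Sesn1 (0.35 ± 0.17). Their mean was -0.001 without the slide term. Interferon response genes were lower by -0.26 ± 0.18 with 22 of 29 lower, including Ifi44 (-0.96 ± 0.41), Bst2 (-1.0 ± 0.49) and Cmpk2 (-0.54 ± 0.26), which was at 0.11 with normexp, where the median of all genes was 0.13. Ribosomal protein genes were lower by -0.24 ± 0.10 with 40 of 42 lower, including Rpl35 (-0.33 ± 0.13), Rpl24 (-0.33 ± 0.13) and Rpl23 (-0.42 ± 0.17).

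These 7 lists passed camera with adjusted p = 3.62e-06 for fatty acids, 0.00111 for adipocytes, 3.62e-06 for macrophages, 0.0293 for smooth muscle, 0.0351 for atrophy, 0.0498 for interferon and 7.83e-07 for ribosomal proteins. None passed with an estimated correlation, where the smallest adjusted p was 0.480. Trained and detrained arrays shared only slide 3, with 4 and 2 arrays, so the exact permutation within slides had 15 arrangements and could not go below p = 0.0667. Within slide 3 the adipocyte mean was 0.66, the macrophage mean 0.62, the ribosomal mean -0.36, the interferon mean -0.40, the smooth muscle mean 0.19 and the atrophy mean 0.15. On that slide the 75th percentile of signal was 133.2, 95.5 and 124.5 on TR 5, TR 7 and TR 8 and 306.5 on TR 6. It was 325.4 on DETR 7 and 185.6 on DETR 8. Array signal was not tested as an explanation of these shifts. No single gene passed limma at adjusted p 0.05 (0 of 20350 features), against 2019 at an unadjusted p under 0.05 and 2 with array weights, among them RGD1562146. With no change, 1018 would be expected under 0.05, and 8 of the 15 arrangements within slides gave at least 2019. Among the smallest p-values were those of Fgf2 (-0.77 ± 0.15), Nxnl2 (-1.0 ± 0.19) and F3, which encodes tissue factor (0.77 ± 0.15), each with adjusted p = 0.149, and of the macrophage-related gene Ms4a4a (1.55 ± 0.31, adjusted p = 0.162). Without TR 6, 14 genes passed, and without TR 2, 3 genes passed.

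The remaining lists did not pass unweighted camera in any comparison. OXPHOS subunits, the proteins of the respiratory chain, differed by a mean of 0.04 ± 0.09 between detrained and sedentary muscle, -0.06 ± 0.08 between trained and sedentary muscle (median 0.02) and -0.10 ± 0.10 between trained and detrained muscle. Citrate cycle genes differed by -0.02 ± 0.06, 0.06 ± 0.05 and 0.07 ± 0.07 in the same order, and slow fibre genes by 0.14 ± 0.06, 0.04 ± 0.05 and -0.10 ± 0.06. Heat shock and chaperone genes differed by 0.09 ± 0.07, -0.05 ± 0.06 and -0.14 ± 0.07, and immediate early and acute exercise genes by -0.08 ± 0.20, -0.12 ± 0.17 and -0.04 ± 0.22. Collagen and matrix genes differed by 0.01 ± 0.11, -0.16 ± 0.09 and -0.17 ± 0.12, and satellite cell and regeneration genes by 0.13 ± 0.05, -0.07 ± 0.05 and -0.21 ± 0.06. Members of the satellite cell list went both ways, and those named were chosen after their values were seen, except Myod1. Adjusted over the list alone, Tnnt2 (0.84 ± 0.19) and Myf5 (0.43 ± 0.14) were higher in trained than in sedentary muscle and Ankrd1 (-1.83 ± 0.63), Myod1 and Cd34 (-0.47 ± 0.14) lower, and 2 members were higher and 2 lower than in detrained muscle. An unplanned test for change in either direction, fry in limma, gave that list adjusted p = 0.939, 0.00276 and 0.0233 in the same order. It also passed for cell cycle genes between trained and sedentary muscle (0.00739) and fibroblast and adipogenic progenitor markers between trained and detrained muscle (0.0233). This test asks whether members change at all, not whether they change more than other genes. In limma 2121 and 2019 features had an unadjusted p under 0.05 in these 2 comparisons, against 1018 expected. Of the splits within slides, 25 of 100 and 8 of 15 gave at least as many. The fry results were not set against such splits. For a shift in 1 direction, fry passed no list in any comparison, with smallest adjusted p of 0.265, 0.307 and 0.263 in the same order. Angiogenesis genes differed by 0.05 ± 0.06, -0.03 ± 0.05 and -0.07 ± 0.07. Adipocyte markers were at 0.36 ± 0.13 in trained against sedentary muscle (camera adjusted p = 0.0698). In the comparison of detrained with sedentary muscle, lists that did not pass had means from -0.29 to 0.14 with adjusted p of at least 0.0599. Between trained and sedentary muscle they had means from -0.16 to 0.36 with adjusted p of at least 0.0698. Between trained and detrained muscle they had means from -0.64 to 0.15 with adjusted p of at least 0.0773. With array weights in camera, added after the data were seen, some of these lists passed at the preset correlation. Weights were not combined with an estimated correlation. With that correlation and no weights, no list passed in any comparison (smallest adjusted p from camera 0.104, 0.688 and 0.48 in the same order). OXPHOS subunits passed between trained and sedentary muscle (adjusted p = 0.000229, mean turned to 0.07) and between trained and detrained muscle (0.00175, mean turned to 0.03). Citrate cycle genes passed in the same comparisons (0.0045 and 9.38e-05, means 0.09 and 0.11), and so did collagen and matrix genes (0.000158 and 0.0191, means -0.27 and -0.32). Adipocyte (0.0104) and smooth muscle (0.00936) markers passed between trained and sedentary muscle, cell cycle genes between trained and detrained muscle (9.38e-05, mean -0.39) and atrophy genes between detrained and sedentary muscle (0.0223, mean -0.04). Called lists that lost their call with these weights were fast fibre genes between trained and sedentary muscle, interferon genes between trained and detrained muscle, and all but the fatty acid list between detrained and sedentary muscle. The mean, the median and the direction of the unweighted test did not share a sign in 6, 7 and 4 of these lists. No list member passed with p adjusted over all genes, and 2, 21 and 24 passed when adjusted over the list alone. The 24 count Dcn, Cd34 and Ms4a2 in more than 1 list each. Ms4a2 was not a fixed member of the lymphocyte list and entered it through the matching of gene names.

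The detrained and the trained differences from sedentary muscle correlated across the 20350 features with r = 0.104, where genes are not independent replicates. Both differences use the same sedentary arrays. In a simulation without any change, the residuals of all 24 arrays from the model were shuffled over groups and slides. Each draw thus kept a shared sedentary reference in the layout, but not the real sedentary arrays in it. The simulation gave a mean r of 0.274 (-0.495 to 0.684 over 100 draws), and 80 of the 100 draws reached the observed value. The covariance was 0.0069 against 0.0163 in the simulation, and r was 0.032 on average when the sedentary arrays were divided between both differences in 24 ways. The correlation was -0.032 after quantile normalization, -0.037 in the authors' normalized table and -0.068 with array row as a further term.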

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

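The tests of array signal and of adipocyte content were written before their results were seen, and all other tests of this part were chosen after. With each gene's slide effect removed, 14 of 252 groups held an array far from the other 7 by Dixon's ratio of gap to range, against 12.6 by chance alone. Myh2 was at 0.81 in SED 3 and at 5.36 or more in the other SED arrays (ratio 0.606), and Myh1 at -0.52 against 3.56 or more (ratio 0.538). Notch3 was highest in SED 3 (-2.25, ratio 0.546) and lowest in DETR 7 (-3.69, ratio 0.575). Dyrk2 was lowest in SED 8 (-0.88, ratio 0.61) and in DETR 5 (-0.05, ratio 0.584), and Ms4a4a was highest in SED 8 (-2.16, ratio 0.539). Ifih1 was lowest in DETR 3 (-5.00, ratio 0.541) and Hmox1 in DETR 8 (-2.58, ratio 0.664). On TR 2, Hadhb (3.37, ratio 0.589) and Myl1 (7.43, ratio 0.543) were highest of the TR arrays and Col2a1 was lowest (-4.38, ratio 0.539). TR 2 also had the highest median spot CV of its group (31.5%, ratio 0.818) and the highest share of spots marked as outliers (2.05%, ratio 0.791).

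Fast fibre genes were many-fold lower on SED 3, TR 1, TR 2, TR 4 and TR 5, where Tnni2 lay at 0.18 to 1.60 against 5.83 to 8.50 on the other 19 arrays. Failure of single probes was first tested on 4 other probes of the same genes; their median difference between trained and sedentary arrays was -0.007 with 2 of 4 lower, which went the way of that explanation, and the test was set aside only after this was seen because 2 of the 4 probes belong to genes without the pattern. Of the other 2, the second probe of Myh2 was at -4.81 to -2.08 on these 5 arrays and at 0.72 or more on the rest, which argues against probe failure for Myh2, and the second probe of Tpm1 was at -0.35 to 0.54 on all 24 arrays without such a gap, so it stays open for Tpm1. Of the 17 genes, 8 were over 2 log2 units lower in SED 3 than in every other sedentary array. SED 3 was picked because fast fibre genes were low there, so this count restates the pattern and decides nothing about probe failure. Of the 5 low arrays, 1 was among the 5 dimmest (1.04 by chance), which argues against dimness. With array signal as a covariate the list's difference was -0.606 ± 0.566 (SE) against -0.924 ± 0.512 without it, which decides nothing. Training stays open as well (exact permutation within slides, p = 0.133), with low values on 4 of 8 TR, 1 of 8 SED and 0 of 8 DETR arrays. SED 3, TR 1, TR 2 and TR 4 lay on slide 2, which held no DETR array, and TR 5 on slide 3. The absence of low DETR arrays therefore cannot be told apart from an effect of slide. Which part of the muscle was sampled was not tested.

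The lower fatty acid list in detrained muscle was set against array signal and adipocyte content. With array signal as a covariate the difference was -0.346 ± 0.141 (SE), against -0.343 ± 0.137 without a covariate. With the adipocyte list's mean as a covariate it was -0.349 ± 0.148. The difference thus persisted with either covariate alone. The adipocyte list is led by Car3 (5.83), Cidea (3.22) and Fabp4 (1.65), and 2 of its 14 genes are in another list. Between trained and sedentary muscle Car3 was lower (-0.253 ± 0.096), while Cfd, Retn, Pck1 and Rbp4 were higher. Each of these passed when adjusted over the list alone. The list's mean is therefore an uncertain measure of adipocyte content, and the test cannot exclude that content. Detraining stays open as a hypothesis, since the exact permutation within slides gave p = 0.0774.

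The lower ribosomal protein list in trained muscle was set against the dim arrays of slide 3. The difference was -0.013 ± 0.032 (SE) within slide 2, where arrays were bright, and -0.298 ± 0.216 within slide 3, so dim arrays may account for it. No biological explanation was tested for this list. Trained and detrained arrays shared only slide 3, so this test could not be made for trained against detrained muscle.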

How the results depend on the processing

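The fits without slide 3, without the 4 noisiest trained arrays and with array weights in camera were chosen after the data were seen. Counts are given as detrained minus sedentary (D), trained minus sedentary (T) and trained minus detrained (R). The cause was not tested for the changes below, except that smaller fits hold fewer arrays and stricter filters fewer genes. The called lists passed in these numbers of settings, then of the 24 fits that left out 1 array. D, of 15 settings: fatty acid 14 and 24, glycolysis 4 and 13, interferon 9 and 22, ribosomal 4 and 11, adipocyte 7 and 18, tendon 4 and 17. T, of 15: fast fibre 6 and 12, ribosomal 11 and 24, cell cycle 10 and 24, macrophage 12 and 24, tendon 12 and 22. R, of 14: fatty acid 10 and 24, atrophy 6 and 17, interferon 4 and 13, ribosomal 11 and 24, macrophage 13 and 24, adipocyte 9 and 24, smooth muscle 5 and 21. The fatty acid list ranged from -0.39 to -0.18 over settings and -0.45 to -0.23 over arrays left out in D. Leaving out 1 array moved these lists over 1.5-fold: without DETR 7, glycolysis D -0.039, adipocyte D -0.12, fatty acid R 0.345 and interferon R -0.165; without DETR 8, fatty acid R 0.062, macrophage R 0.275 and smooth muscle R 0.407; without SED 1, tendon D -0.777; without TR 7, ribosomal T -0.092. Dim arrays limit what can be measured, with 47.9% of probes well above background on TR 7 and 85.4% on DETR 1. With normexp the median of all genes moved to 0.152 in T and 0.128 in R, from 0.014 and -0.031, so the cell cycle list at 0.095 in T and Cmpk2 at 0.105 in R lie below it.

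Genes called were 0 in each comparison. They were 15 (D), 107 (T) and 2 (R) with array weights, 1 (D), 2 (T) and 1 (R) without the 4 noisiest trained arrays, and, in T, 2 with normexp, 1 in the authors' normalized table, 8 with slide and array row, 1 without slide 3, 1 at adjusted p under 0.10 and 2 with all probes. With only the groups compared, R had 1. Leaving out each array gave 0 to 3 (T) and 0 to 14 (R, TR 6). Lists called were 6 (D), 5 (T) and 7 (R), and a list count not given below changed by at most 1.5-fold. They were 2 (D), 9 (T) and 10 (R) with array weights, 10 (D), 12 (T) and 9 (R) with normexp, 10 (R) without the 4 noisiest trained arrays, 3 (D) after quantile normalization, 3 (D) without slide 3, 3 (D) within slide 1, and 2 (D), 2 (T) and 4 (R) with probes above background on all arrays. An estimated correlation gave 0 in all 3, no filter 8 (T), no slide term 11 (T), slide as a random block 8 (T) and slide with array row 8 (T). Leaving out each array gave 2 to 8 (D), 3 to 9 (T) and 4 to 12 (R). The number changed over 1.5-fold without DETR 3, DETR 6 or TR 2 (D), SED 2, SED 6, SED 8 or DETR 8 (T) and SED 2 or DETR 8 (R); which lists were called changed without other arrays too, as the numbers per list above show.

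The replicate numbers do not pair the arrays: with slide removed, 1, 1 and 0 of 8 same-numbered pairs correlated over 0.1, and 1, 0 and 0 arrays correlated best with their own number. With the replicate number as a block, 4 genes (T) and 35 genes (R) passed, lists were 3 (D) and 3 (R), and the direction turned for Hmox1 (-0.066) and Myod1 (0.015) in D and Hk2 (0.002), Cs (-0.087) and Hspa1b (-0.172) in T.

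Directions also turned as follows. The correlation of both effects was -0.032 after quantile normalization, -0.037 in the authors' table and -0.068 with array row. Without the 4 noisiest trained arrays: Cs D -0.035, Slc2a4 T 0.012, Fbxo32 T -0.024. With normexp: Cs T -0.04. Authors' table: Myh7 D -0.099, Mrc1 R -1.194. Quantile: Myh7 D -0.11. Array row: Cs D -0.018, Myh2 D 0.625, Myh4 D 0.391, Myod1 D 0.012, Fbxo32 T -0.01. Without slide 3, and in D also within slide 1: Slc2a4 D 0.008, Cs D -0.086, Myh2 D 0.43, Myh4 D 0.51, Vegfa D -0.052 and the glycolysis list D 0.011. Without slide 3: Slc2a4 T 0.062 (also within slide 2), Cmpk2 R 0.016, Notch3 R -0.044. No slide term: Pck1 D 0.033, Slc2a4 D 0.022, Myh2 D 0.908, Myh4 D 0.486, Trim63 D 0.014, Cs T -0.18, Myh7 T 0.242, Hspa1b T -0.038, Actg2 R -0.109, and the lists glycolysis D 0.074, adipocyte D 0.01, fatty acid R -0.034 and atrophy R -0.001. Within slide 3: Ppargc1a D -0.036, Hk2 D -0.035, Hmox1 D -0.134, Myog D -0.006, Nr4a3 D 0.477, Ppargc1a T -0.011, Hk2 T 0.035, Cs T -0.158. Leaving out each array gave, in D, Ppargc1a -0.039 to 0.257, Slc2a4 -0.1 to 0.048, Cs -0.021 to 0.099, Myh2 -0.549 to 0.243, Myh4 -0.405 to 0.265, Hmox1 -0.002 to 0.19, Myod1 -0.148 to 0.038 and Nr4a3 -1.101 to 0.372, and, in T, Cs -0.01 to 0.104, Hmox1 -0.001 to 0.326 and Fbxo32 -0.004 to 0.12.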

Other observations

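The fit with array weights was planned; the splits, the fit without slide 3 and the genes named here were chosen after the results were seen. When limma weighted each array by its quality, 107 genes passed between trained and sedentary muscle, 52 higher and 55 lower, and 96 of them had an unadjusted p under 0.05 without weights. Lower ones included Rrm2 (log2 difference -1.29 ± 0.22, SE, adjusted p = 0.00899), Cdk1 (-0.92 ± 0.17), Kif22 (-0.76 ± 0.14), Clu (-0.92 ± 0.14) and the matrix gene Postn (-1.16 ± 0.26), and they were not tested as a group. Higher ones included the complement gene C6 (1.35 ± 0.21), Tnnt2, which encodes cardiac troponin T (0.83 ± 0.18), and Myl1 (0.41 ± 0.07). TR 2, TR 5, TR 7 and TR 8 had weights of 0.126, 0.23, 0.137 and 0.161 against 0.684 to 2.993 on the other TR arrays, so the weighted trained mean rests mainly on 4 arrays, 3 of them on slide 2. Without slide 3, 1 gene passed.

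The arrays of each comparison were split into groups of the same sizes in 100 ways, the real one included. With array weights, 1 of 100 splits, the real one, gave as many as 107 genes between trained and sedentary muscle (highest other 39). These splits ignored the slides, so the arrays were also split with each slide's group sizes kept, again in 100 ways. There 1 of 100, the real one, gave as many as 107 (highest other 32), which argues against chance for that count taken alone. The low weights of TR 2, TR 5, TR 7 and TR 8 had no match in SED, where the lowest was 0.916. The splits therefore cannot tell a group difference in expression from one in array quality. Without these 4 arrays, 2 genes passed in this comparison. The count of 107 was looked at because it was the largest over up to 19 alternative settings in each of 3 comparisons, for which no correction was made. For the 15 weighted genes between detrained and sedentary muscle 5 splits gave as many (highest other 869), and for the 2 between trained and detrained muscle 12 did (highest other 265), so chance is not excluded. Without weights 0 genes passed in each comparison, so 100, 100 and 100 splits gave as many, with highest others of 1, 309 and 1892. The split with 309 genes set SED 3, TR 1, TR 2, TR 4 and TR 5 with SED 6, TR 7 and TR 8. The first 5 of these are the arrays low in fast fibre genes. The split with 1892 set TR 2, TR 7 and TR 8 with 5 DETR arrays of slide 1. Both splits thus kept TR 2, TR 7 and TR 8 together, which had the lowest weights (0.126, 0.137 and 0.161). These counts point to structure among the arrays, which may lie in the samples or in array quality. For the lists, 58 splits gave at least the 6 of detrained against sedentary muscle (highest other 13), 48 at least the 5 of trained against sedentary muscle (highest other 10) and 23 at least the 7 of trained against detrained muscle (highest other 10), so chance is not excluded for the number of lists. With each slide's group sizes kept, 12 of 100 splits gave at least the 15 weighted genes of detrained against sedentary muscle (highest other 788), and 100 and 100 gave as many as the 0 unweighted genes in the comparisons with sedentary muscle (highest others 2 and 3). For the lists, 50 of 100 gave at least the 6 of detrained against sedentary muscle (highest other 15) and 50 of 100 at least the 5 of trained against sedentary muscle (highest other 9). Any split reaches a count of 0, so these counts of unweighted genes decide nothing. Trained against detrained muscle has only 15 such arrangements, too few to decide on weighted genes or lists. Of them, 6 gave as many weighted genes (highest other 167) and 5 as many lists (highest other 9). All 15 reached the 0 unweighted genes (highest other 5660).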
